A study of Mus musculus with 34 samples.

How the data were processed

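Messenger RNA from the blood of wild-type mice was sequenced in 4 groups defined by the treatment label: phosphate-buffered saline (PBS), ALY688, lipopolysaccharide (LPS, a component of the outer membrane of Gram-negative bacteria that is sensed through TLR4), and ALY688 with LPS. ALY688 is described in the series title as an adiponectin receptor agonist. Total RNA was isolated with a column kit, messenger RNA was captured on poly-T beads and fragmented, and cDNA was primed with random hexamers, per the labels' protocols. The protocol covers a strand-specific and a non-strand-specific library without saying which was made. Doses, times of sampling, sex and age are not given in the sources used here. Each label names a numbered mouse, so a replicate is 1 animal. Of 34 labelled samples, 30 had counts; PBS mouse 10 and LPS mice 3, 4 and 5 were not analysed here.

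The values are whole-number read counts per gene, not normalized, as the authors deposited them, in 1 table per mouse with 54532 gene IDs. Reads were aligned with HISAT2 2.0.5 and counted with featureCounts 1.5.0-p3, per the submitters' processing notes. The genome build, the annotation release and the strand setting of the counting are not given in the sources used here. Gene symbols and coordinates were taken from GENCODE M21 on GRCm38, which held 54409 of the 54532 IDs, and the other 123 kept their IDs. Without a stated strand setting, reads of overlapping and antisense genes cannot be told apart. How reads shared by near-identical genes were counted is not given either, so these genes are uncertain: Klra8 and Klra4, Hspa1a and Hspa1b, Oas1a, Ly6c2, Stfa2l1, the Saa and globin genes, Ighg2c, and the processed pseudogene Rps12-ps4.

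Totals ran from 9554964 to 17338214 counts per library. Globin genes took 18.4% to 64.3% of the counts, so the depth left for other transcripts differed between libraries. The floor of detection, 3 counts of a library's total, lay between 0.173 and 0.314 CPM (counts scaled to a common library total), before the TMM scaling described below. It covers counting error only, since reads carry no molecular identifiers. Levels in the results are TMM-scaled, and on that scale 3 counts stood at 0.0725 CPM in LPS mouse 6 and at 0.789 CPM in ALY688 mouse 7. No pair of libraries within a group differed by as little as sampling noise: the chi-square per degree of freedom over genes was at least 8.02 (ALY688 mice 4 and 5), so each library was counted as 1 replicate.

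Counts were scaled with TMM factors, genes with low counts were removed with filterByExpr, and groups were compared with the quasi-likelihood F-test of edgeR 4.0.16 (glmQLFit with robust estimation, glmQLFTest, two-sided) in R 4.3.3. A gene passed at a Benjamini-Hochberg adjusted p below 0.05. The 5 comparisons were ALY688 against PBS, ALY688 with LPS against LPS, LPS against PBS, ALY688 with LPS against ALY688, and the interaction of both treatments; only the groups compared entered each fit, and all 4 entered the interaction. The interaction is the log2 fold change for ALY688 under LPS minus that without LPS. Levels are TMM-scaled CPM with the SD between mice, and fold changes are log2 values with their standard error (SE). Adjusted p-values of genes come from edgeR unless another tool is named.

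Gene lists were tested with camera from limma 3.58.1 at its preset correlation of 0.01, adjusted over the lists of a comparison, beside camera with an estimated correlation and fry. Camera asks whether the genes of a list moved more than the other genes. Fry asks whether they moved, on balance, one way. Of 37 lists covering blood cell types, inflammation, adiponectin signalling, metabolism, stress responses and other tissues, 36 had at least 3 tested members in some comparison. A score per library, the mean log2 CPM (prior count 2) over a list, was compared between groups for the 10 blood cell type lists and the globin share with exact permutation tests, two-sided, 11 in each family. The effects of ALY688 without and with LPS were correlated across genes and set against relabelled mice within each experiment, with 100 labellings including the real one.

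The comparisons, tests, gene lists and the rule for the genes named were fixed before the data were examined, except the tests of scores per library, which were added later. The rule names, per comparison, the 8 genes that rose and the 8 that fell with the smallest unadjusted p, leaving out predicted genes and genes under 1 CPM on average in both groups, or the 3 nearest in each direction where none passed. It adds up to 4 members of each described list with the smallest unadjusted p, and 10 genes whatever their values: Adipor1, Adipor2, Cdh13, Tnf, Il1b, Il6, Il10, Cxcl10, Lcn2 and Tlr4. A list is described where its camera test or any member passed, or where it covers a blood cell type, inflammation or adiponectin signalling. Clone-style symbols were treated as predicted genes, a reading of the rule made after the values had been seen. No fitted fold change is given against a group at or near 0 counts; its level and counts are given.

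The gene fits and camera were tested on simulated counts drawn from the real means and library sizes, with 200 genes changed by known amounts. Each gene was drawn independently, so the preset correlation of camera was not put to the test. The recoveries hold for few changed genes and do not describe power where many genes passed, as in the LPS comparisons. Genes changed 2-fold were recovered at 65.7% in ALY688 against PBS, 25.4% in ALY688 with LPS against LPS, 26.9% in LPS against PBS, 73.1% in ALY688 with LPS against ALY688 and 26.9% in the interaction. Genes changed 4-fold were recovered at 98.5%, 72.7%, 81.8%, 95.5% and 72.7%, in the same order.

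The alternatives chosen beforehand were RLE size factors, DESeq2 1.42.0, limma-voom with sample quality weights, no filter and a stricter filter on low counts, globin genes left out, 1 surrogate variable (sva 3.50.0), the mouse number as a block, all 4 groups in every fit, camera with an estimated correlation, the correlation over genes with a mean log2 CPM above 3, and each library left out in turn. Chosen after seeing the data were library size scaling without TMM, leaving out libraries with fewer than 16000 genes with a count, and the globin percentage as a covariate, as well as the use of RLE size factors for the gene lists and of a surrogate variable for the gene lists and the correlation. Some single genes of the lists are not reported here. Figures were drawn with matplotlib 3.10.9 and tables handled with pandas 2.3.3 in Python 3.11.15.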

Results

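Blood transcriptomes were measured in 9 mice given PBS, 10 given ALY688, 4 given LPS and 7 given ALY688 with LPS. The series text describes 2 experiments, a search for blood-borne markers of ALY688 in mice with or without it, and a test of its anti-inflammatory effects in mice given a sublethal dose of LPS. It speaks of plasma for the first and of whole blood for the other, while every sample is labelled blood. Since mice with and without LPS may belong to separate experiments, treatment and experiment cannot be told apart in any comparison across LPS. Total counts ran from 9554964 to 11289689 per library with PBS, 10893714 to 12514008 with ALY688, 10914821 to 17338214 with LPS and 10087871 to 15349120 with both.

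Globin transcripts, the haemoglobin mRNA carried by young red cells, made up 56.3% ± 6.22 (SD, n = 9) of the counts with PBS and 49.2% ± 6.51 (n = 10) with ALY688. The share was 30.4% ± 10.4 (n = 4) with LPS and 40.5% ± 10.96 (n = 7) with both. The difference of −7.09 points for ALY688 without LPS had an exact two-sided permutation p of 0.0291, which became 0.321 over the 11 measures tested. Under LPS the difference was +10.1 points (exact permutation p = 0.173, adjusted 0.633). Genes with at least 1 count numbered 14351 to 19746 per library, and PBS mice 5, 6 and 9, ALY688 mouse 7, and mice 6 and 8 of the combined group had fewer than 16000, with globin shares of 53.5% to 64.3%. The first principal component, 41.7% of the variance, placed the 19 libraries without LPS between −58.2 and −29.4 and the 11 with LPS between 37.8 and 95.1. Mice 4 and 8 of the combined group lay lowest among the latter, at 37.8 and 47.8.

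**Figure D1:**
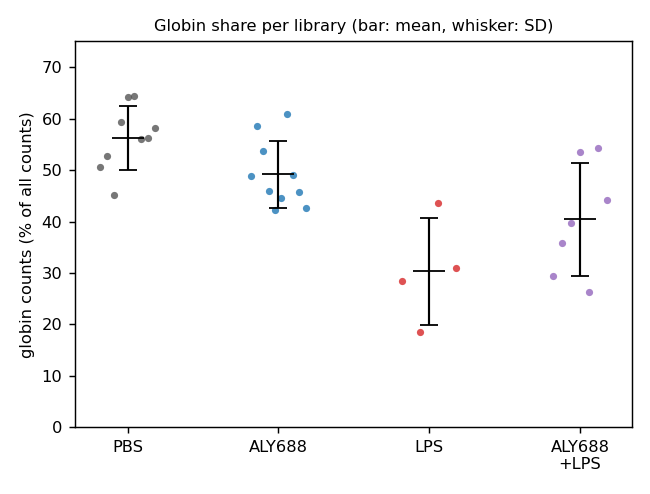
Globin transcripts as a percentage of all counts in each library, with the 4 groups on the x axis, dots for mice, bars for the group mean and whiskers for the SD. The means were 56.3% with PBS, 49.2% with ALY688, 30.4% with LPS and 40.5% with both treatments, and the range with LPS, 18.4% to 43.7%, lay below that with PBS, 45.1% to 64.3%.

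The first comparison asked which blood transcripts differ after ALY688 alone. No gene passed the threshold. None of the genes of inflammation and of adiponectin signalling passed. Tnf, a pro-inflammatory cytokine, lay at 1.502 ± 0.567 CPM (SD, n = 9) with PBS and 1.96 ± 0.812 (n = 10) with ALY688. Il1b, another such cytokine, lay at 108 ± 61.2 and 73.8 ± 27.6. Lcn2, a neutrophil protein that binds bacterial iron carriers, lay at 14.3 ± 7.27 and 14.2 ± 8.89, and Tlr4, the LPS receptor, at 5.63 ± 1.97 and 5.05 ± 0.979. Adipor2 and Adipor1, the adiponectin receptors, lay at 31.9 ± 3.53 and 34.7 ± 3.18 CPM, and at 1956 ± 1064 and 1634 ± 1709. The log2 fold changes were 0.33 ± 0.25 (SE) for Tnf, −0.60 ± 0.30 for Il1b, −0.04 ± 0.35 for Lcn2 and −0.16 ± 0.18 for Tlr4. They were −0.08 ± 0.41 for the interferon-induced chemokine Cxcl10, 0.09 ± 0.07 for Adipor2 and −0.27 ± 0.46 for Adipor1, with adjusted p from 0.442 (Il1b) to 0.968 (Lcn2). Mouse 7 of the ALY688 group held 6469 CPM of Adipor1, and without it the log2 fold change of Adipor1 was −0.91 (adjusted p = 0.148). Across all groups, libraries with fewer than 16000 genes with a count held the highest Adipor1 levels, 2591 to 6469 CPM, against at most 1631 elsewhere. Their TMM factors were the lowest, 0.349 to 0.631. Differences in Adipor1 in any comparison were therefore not separated from these properties of the libraries. Il10 had 0 counts in all 19 libraries. Cdh13, the adiponectin-binding T-cadherin, and Il6 were low. They had 7 counts in 3 of 9 and 11 in 3 of 10 libraries for Cdh13, and 8 in 3 of 9 and 21 in 6 of 10 for Il6.

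Among the genes nearest the threshold in ALY688 against PBS, none of which passed (each adjusted p = 0.442), means were higher for Zc3h6, a zinc finger protein (2.50 ± 1.11 to 4.92 ± 1.27 CPM, log2 fold change 0.90 ± 0.22). They were also higher for Phf20, a chromatin reader (9.58 ± 2.09 to 13.6 ± 2.01, 0.47 ± 0.11), and Slc37a2, a sugar-phosphate transporter (7.43 ± 1.14 to 10.0 ± 0.828, 0.40 ± 0.10). Means were lower for Ttc27 (8.46 ± 1.40 to 6.20 ± 0.973, −0.48 ± 0.13), Bag3, a co-chaperone of Hsp70 (8.34 ± 2.86 to 4.85 ± 1.49, −0.81 ± 0.23), and Ppt2, a lysosomal thioesterase (7.31 ± 2.15 to 4.65 ± 1.10, −0.66 ± 0.19). Of 11708 genes tested, edgeR called 0, with 1250 at an unadjusted p under 0.05 against 585 expected for independent genes. As many such genes were reached in 6 of 100 labellings of the mice, the real one included. The other labellings had a median of 249, and an excess over chance was not shown. DESeq2 called 0 with 1656 such genes, and limma-voom 0 with 916. In edgeR their number was 422 without the libraries of few detected genes, 379 with 1 surrogate variable and 293 with the globin covariate. These 3 numbers lay below 585, and the mice were not relabelled in these settings. The 95% interval had a median width of ±0.38 in log2, and lay within 2-fold either way for 81.8% of the genes. Without TMM scaling the median of all genes moved by 0.47, and changes are reported relative to that median.

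Gene lists went in both directions after ALY688 alone, and 14 of 36 passed the camera test at the preset correlation, 2 upward and 12 downward. None held with an estimated correlation (adjusted p = 0.707 for each of the 14), and fry called 0, with a smallest adjusted p of 0.179. Scores per mouse did not pass for any of the 10 blood cell type lists in exact permutation tests, with platelet scores 0.83 lower (p = 0.126, adjusted 0.404) and B cell scores 0.32 higher (p = 0.144, adjusted 0.404). Platelet markers were lower in 23 of 23 members (median log2 fold change −1.02, camera adjusted p = 2.45e-09), with the adhesion genes Selp at −1.19 ± 0.48 and Gp1ba at −1.08 ± 0.45, Treml1 at −1.20 ± 0.52 and the signalling regulator Rgs18 at −0.96 ± 0.42. The 5 endothelial and skin transcripts were all lower (median −0.86, adjusted p = 0.01002), among them Pecam1 (−0.79 ± 0.34) and Vwf (−0.96 ± 0.48), which platelets also carry. Type I interferon-stimulated genes were lower in 26 of 33 (median −0.34, adjusted p = 5.37e-05), with Oasl2 at −0.73 ± 0.26 and Irf7, the regulator of interferon production, at −0.87 ± 0.34, and without TMM their median was 0.27, which is −0.23 relative to all genes. B cell markers were higher in 24 of 24 (median 0.21, adjusted p = 0.000164), with Cd72 at 0.42 ± 0.17 and the lineage factor Pax5 at 0.42 ± 0.19. Genes of sterol and fatty acid synthesis were higher in 18 of 22 (median 0.25, adjusted p = 0.000255), with the desaturase Scd2 at 0.42 ± 0.16 and Srebf2, the main activator of sterol synthesis genes, at 0.34 ± 0.14. Adjusted over the list alone, 2 members of all lists passed: Klra8, an activating NK cell receptor, rose (0.72 ± 0.18, 6.44 ± 1.98 to 10.9 ± 3.32 CPM), and Bag3 of the heat shock list fell. No member of any list passed over all genes.

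The other lists that passed downward after ALY688 alone turned upward in their raw median without TMM, and their values relative to all genes stayed below 0. They were erythroid genes (23 of 29 lower, median −0.31, 0.12 without TMM, beside a globin share 7.09 points lower), cytoplasmic ribosomal proteins (42 of 48, −0.13, 0.36), and autophagy genes (16 of 22, −0.32, 0.21). Further lists were the nuclear-encoded respiratory chain (34 of 42, −0.12, 0.36), and neutrophil markers (18 of 22, −0.25, 0.42). The rest were fatty acid oxidation and PPAR target genes (18 of 22, −0.13, 0.35), oxidative stress and NRF2 target genes (18 of 22, −0.25, 0.29), mitochondrially encoded genes (9 of 10, −0.37, 0.24) and monocyte markers (17 of 21, −0.11, 0.31). Members nearest the threshold were the autophagy gene Atg7 (−0.80 ± 0.31), the peroxidase Prdx6 (−1.05 ± 0.42), and the neutrophil receptor Fpr2 (−0.47 ± 0.23). Others were F13a1, a transglutaminase on the monocyte list (−1.21 ± 0.48, against a list median of −0.11), Cox5a of the respiratory chain (−1.04 ± 0.43), mt-Atp6 (−0.68 ± 0.28) and the iron uptake receptor Tfrc (−0.35 ± 0.15). Of these calls, only the neutrophil, mitochondrial and monocyte calls ended on leaving out single libraries. The others stayed in every leave-out, though several of their medians moved. The neutrophil call ended without PBS mouse 7 (median −0.17, adjusted p = 0.123), PBS mouse 9 (−0.06, 0.171) or ALY688 mouse 8 (−0.19, 0.0896). The mitochondrial call ended without PBS mouse 5 (−0.25, 0.0510) or 9 (−0.19, 0.0561), and the monocyte call in 10 of 19 leave-outs (PBS mice 1, 4, 5, 7 and 8, ALY688 mice 1, 4, 5, 7 and 10). The monocyte median ran from −0.06 without ALY688 mouse 10 and −0.07 without PBS mouse 7 to −0.16 without PBS mouse 6, −0.17 without PBS mouse 2 and −0.20 without ALY688 mouse 3. Without ALY688 mouse 7 the medians became −0.95 for erythroid, −0.42 for NRF2 and −0.63 for autophagy genes. Without PBS mouse 9 they became −0.13, −0.13 and −0.18, and −0.67 for platelet markers. The erythroid median became −0.13 without PBS mouse 5 and −0.21 without PBS mouse 6, the NRF2 median −0.10 without PBS mouse 5, the ribosomal −0.08 without PBS mouse 6, the fatty acid oxidation −0.21 without PBS mouse 3, and the interferon −0.19 without PBS mouse 7. With the 4 libraries of few detected genes left out, the neutrophil (median −0.04, adjusted p = 0.719), mitochondrial (−0.06, 0.240) and endothelial (−0.21, 0.472) calls ended, and the platelet median was −0.29. With the globin percentage as a covariate, only the sterol list (0.15, 0.00691) kept its call among the 14, leaving aside erythroid genes, which hold the globins the covariate measures. With 1 surrogate variable 10 of the 14 calls ended, among them platelet (−0.02, adjusted p = 0.364) and B cell markers (−0.01, 0.681), while the interferon (−0.12, 0.00377), sterol (0.18, 0.00103) and ribosomal (−0.10, 0.00103) calls stayed and the erythroid list passed upward (0.22, 0.00885). Without TMM the neutrophil, monocyte, fatty acid oxidation, respiratory chain, mitochondrial and ribosomal calls ended.

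Lists of inflammation did not pass after ALY688 alone. Median log2 fold changes were −0.08 for 11 cytokines and chemokines (camera adjusted p = 0.518), 0.07 for 23 NF-kB target genes (0.460), and 0.03 for 23 TLR4 signalling components (0.909). They were −0.05 for 12 inflammasome components (0.518), −0.05 for 22 interferon-gamma-induced genes (0.292) and −0.15 for 18 feedback inhibitors (0.0696). Their nearest members were Nfkbie, an NF-kB inhibitor (0.29 ± 0.11), Tlr2 (−0.37 ± 0.16), the GTPase Ifi47 (−0.38 ± 0.13) and Socs3, an inhibitor of cytokine signalling (−0.31 ± 0.14). The 19 tested genes of adiponectin receptors and downstream signalling had a median of 0.03 (adjusted p = 0.884), with Prkab2, a subunit of AMP-activated kinase, at −0.91 ± 0.36 and the carboxylase Acaca at 0.38 ± 0.16. T cell (0.09, 0.250), NK cell (0.14, 0.0696), dendritic cell (0.19, 0.292) and immature neutrophil granule genes (−0.04, 0.885) also missed the threshold. The median, mean and test differed in sign for the TLR4, immature granule, adiponectin, muscle and adipocyte lists.

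The next comparison asked what ALY688 changes in mice given LPS. No gene passed the threshold. Lcn2 lay at 1028 ± 534 CPM with LPS (n = 4) and 1207 ± 529 with ALY688 and LPS (n = 7), and Il1b at 431.6 ± 198 and 492.7 ± 111. Tnf lay at 19.95 ± 8.30 and 20.1 ± 10.4, Tlr4 at 24.8 ± 7.85 and 26.3 ± 5.23, and Cxcl10 at 3.45 ± 1.26 and 4.17 ± 2.18. The log2 fold changes were 0.23 ± 0.48 for Lcn2, 0.20 ± 0.33 for Il1b, 0.04 ± 0.43 for Tnf, 0.10 ± 0.21 for Tlr4 and 0.30 ± 0.39 for Cxcl10, with adjusted p of at least 0.929. Il10, an anti-inflammatory cytokine, had a count in all 11 libraries, at 1.06 ± 0.419 and 1.09 ± 0.765 CPM (log2 fold change 0.14 ± 0.58). In mice 4 and 8 of the combined group it had 1 count each, under the floor of 3 counts. Cdh13 was low, at 7 counts in 4 of 4 and 7 in 5 of 7 libraries. Il6 had 12 counts in 3 of 4 LPS libraries and 70 in 5 of 7 with both, of which mouse 1 held 41 (1.69 CPM) and mouse 7 held 23 (0.822 CPM). Adipor2 lay at 62.0 ± 11.997 and 61.0 ± 6.16 CPM (−0.01 ± 0.14) and Adipor1 at 828 ± 520 and 1728 ± 1773 (1.10 ± 0.74). Mouse 8 of the combined group held 5416 CPM of Adipor1, without which its log2 fold change was 0.42, and it was −0.04 without the libraries of few detected genes. Arg1, an arginase of alternatively activated myeloid cells, had a mean of 3.27 ± 2.27 against 15.1 ± 16.7 CPM (2.23 ± 0.92).

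The genes nearest the threshold under LPS, none of which passed (each adjusted p = 0.913), were higher with ALY688 for Trac, the constant region of the T cell receptor alpha chain (6.50 ± 1.23 to 10.1 ± 1.49 CPM, log2 fold change 0.65 ± 0.15). They were also higher for Cd8b1, a co-receptor of cytotoxic T cells (5.10 ± 0.878 to 8.83 ± 2.51, 0.80 ± 0.23), and Zfp1 (0.65 ± 0.19). Means were lower for E2f7, a repressor of cell cycle genes (2.71 ± 1.57 to 1.00 ± 0.197, −1.44 ± 0.35), Tspoap1 (3.59 ± 1.47 to 1.51 ± 0.517, −1.21 ± 0.31) and the kinesin Kifc5b (−0.92 ± 0.23). Of 12741 genes tested, edgeR called 0, with 463 at an unadjusted p under 0.05 against 637 expected for independent genes. As many such genes were reached in 48 of 100 labellings of the mice, the real one included. DESeq2 called 0 with 635 such genes, and limma-voom 0 with 1098. In edgeR their number was 309 without the libraries of few detected genes, 309 with the globin covariate and 49 with the mouse number as a block. The block compared only mice 6, 7 and 8, whose numbers occur in both groups, so the 49 do not speak for the other libraries. The 95% interval had a median width of ±0.53 in log2 and lay within 2-fold either way for 67.5% of the genes. For the other genes a 2-fold change was not excluded. Simulated 2-fold changes were recovered at 25.4% with these numbers of mice. Without TMM the median of all genes moved by −0.49.

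Under LPS, 11 of 36 lists passed the camera test at the preset correlation, 9 upward and 2 downward, none with an estimated correlation (adjusted p = 0.789 for each), and fry called 0 (smallest adjusted p = 0.765). No blood cell type score per mouse passed in exact permutation tests, with T cell scores 0.41 higher (p = 0.0545, adjusted 0.600), NK cell scores 0.49 lower (p = 0.167, adjusted 0.633) and erythroid scores 0.94 higher (p = 0.279, adjusted 0.720). T cell markers were higher with ALY688 in 20 of 24 members (median 0.51, camera adjusted p = 1.503e-10), with Cd5 at 0.86 ± 0.27 and the transcription factor Lef1 at 0.86 ± 0.32. Without TMM the median was −0.08, which is 0.41 relative to all genes. Trac rose, as the only member of any list to pass adjusted over the list alone, and none passed over all genes. Proliferation genes were lower in 24 of 26 (median −0.66, adjusted p = 1.503e-10), with the mitotic kinase Aurkb at −1.06 ± 0.35, Cdc20 at −0.99 ± 0.35 and the kinesin Kif11 at −0.88 ± 0.33. NK cell and cytotoxic markers were lower in 18 of 18 (median −0.35, adjusted p = 2.43e-07), with Klra8 at −0.85 ± 0.25, the transcription factor Eomes at −0.81 ± 0.27 and perforin, Prf1, at −0.61 ± 0.29. Erythroid genes were higher in 30 of 30 (median 1.29, adjusted p = 5.16e-08), with the globin Hba-a2 at 1.80 ± 1.05, beside a globin share 10.1 points higher.

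The remaining lists that passed under LPS were all higher with ALY688, and without TMM each fell below 0 in its raw median while staying above that of all genes. They were ribosomal proteins (43 of 48 higher, median 0.21, adjusted p = 2.46e-06, −0.47 without TMM), and type I interferon-stimulated genes (28 of 34, 0.37, 0.000368, −0.08). Others were platelet markers (23 of 23, 0.52, 0.000399, −0.07), and B cell markers (23 of 24, 0.51, 0.000897, −0.18). The rest were neutrophil markers (20 of 24, 0.23, 0.00374, −0.10), autophagy genes (17 of 22, 0.27, 0.00469, −0.28) and glucocorticoid-responsive genes (11 of 13, 0.33, 0.00950, −0.02). Examples were Rpl24 (0.94 ± 0.30), the interferon-induced exonuclease Isg20 (1.40 ± 0.85), Selp (0.52 ± 0.31), the B cell antigen Ms4a1 (0.73 ± 0.44), the neutrophil receptor Trem1 (0.32 ± 0.25) and the autophagy receptor Sqstm1 (0.80 ± 0.46). Single libraries carried several of these calls. Without LPS mouse 6 the interferon (median 0.18, adjusted p = 0.465), neutrophil (0.02, 0.743), platelet (0.23, 0.348), autophagy (0.20, 0.277) and glucocorticoid (0.25, 0.118) calls ended, and the NK median became −0.17. Without LPS mouse 2 the neutrophil (0.11, 0.149), autophagy (0.18, 0.0816) and glucocorticoid (0.20, 0.207) calls ended, and medians became −0.42 for proliferation, 0.33 for platelet and 0.35 for ribosomal genes. Without LPS mouse 7 the B cell call ended (0.31, 0.337), and medians became 0.69 for interferon, 0.48 for neutrophil, 1.03 for platelet, 2.01 for erythroid and 0.12 for ribosomal genes. The ribosomal call ended without LPS mouse 8 (0.10, 0.0607). Leaving out mice of the combined group ended the B cell call without mouse 4 (0.10, 0.346), and the neutrophil call without mouse 7 (0.16, 0.0729). It also ended the platelet (0.14, 0.0585) and autophagy (0.15, 0.0712) calls without mouse 8, and the glucocorticoid call without mouse 1 (0.17, 0.1003) or 3 (0.23, 0.0877). Without mouse 8 the erythroid median became 0.58 and the ribosomal 0.12, without mouse 1 the neutrophil median became 0.16, and without mouse 6 the interferon median became 0.20. With the libraries of few detected genes left out, the erythroid (0.03, adjusted p = 0.249), platelet (0.03, 0.343), interferon (0.08, 0.113), autophagy (0.05, 0.359) and ribosomal (0.01, 0.119) calls ended, while the T cell (0.51, 8.57e-14) and proliferation (−0.65, 2.66e-12) calls stayed. With the globin covariate the platelet list passed downward (−0.39, 9.45e-08), and the NK cell (−0.03, 0.0805), interferon (0.01, 0.393), neutrophil (0.14, 0.166) and autophagy (−0.07, 0.102) calls ended. With 1 surrogate variable the interferon (0.08, 0.0708), erythroid (0.07, 0.178) and autophagy (0.01, 0.922) calls ended and the platelet list passed downward (−0.16, 0.0441), and without TMM the ribosomal call ended (0.276).

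Lists of inflammation did not pass between ALY688 with LPS and LPS. Medians were 0.20 for 23 cytokines and chemokines (camera adjusted p = 0.278), 0.11 for 28 NF-kB target genes (0.278), −0.01 for 25 TLR4 signalling components (0.928), 0.07 for 12 inflammasome components (0.568), 0.05 for 23 interferon-gamma-induced genes (0.583) and 0.09 for 20 feedback inhibitors (0.553). Their nearest members went both ways, with Ccl4, a monocyte-attracting chemokine, at −0.81 ± 0.28, Il1a at 1.13 ± 0.42, the guanylate-binding protein Gbp5 at 0.32 ± 0.16 and haem oxygenase, Hmox1, at −0.49 ± 0.30. Monocyte markers had a median of −0.06 (0.985), dendritic cell markers −0.09 (0.993) and the adiponectin list −0.03 (0.916), with the receptor Ppard at −0.27 ± 0.15. Immature neutrophil granule genes had a median of −0.36 (0.139). The protease Prtn3 ran from 0.956 to 69.8 CPM among the 4 LPS mice and had a mean of 1.86 ± 0.583 in the combined group. The median, mean and test differed in sign for the TLR4, monocyte, dendritic, adiponectin, respiratory chain, circadian and endothelial lists.

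**Figure D2:**
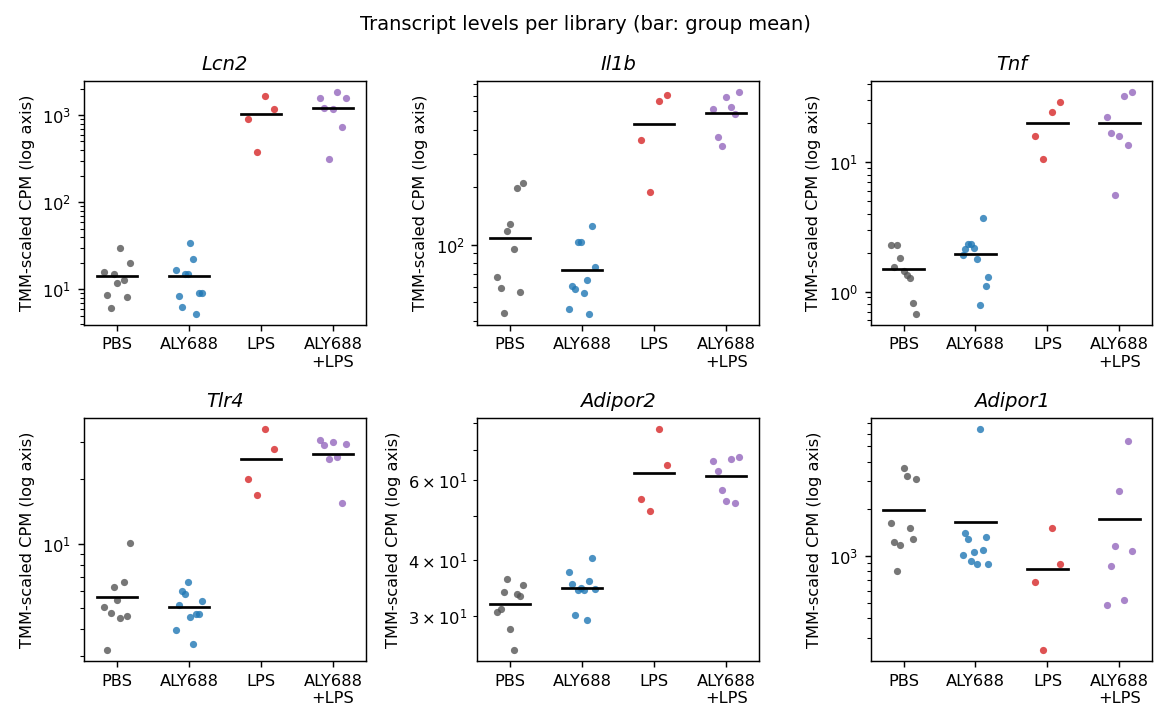
TMM-scaled CPM on a log axis of Lcn2, Il1b, Tnf, Tlr4, Adipor2 and Adipor1 in each library, with the 4 groups on the x axis, dots for mice and bars for the group mean. Lcn2 averaged 14.3 CPM with PBS, 14.2 with ALY688, 1028 with LPS and 1207 with both, and Adipor2 averaged 31.9, 34.7, 62.0 and 61.0.

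As the background to the treated comparisons, LPS was set against PBS without ALY688. Inflammatory and neutrophil transcripts rose, and B and T cell transcripts fell. RNA came from all blood cells together. A change in the mix of cells was therefore not separated from a change within cells, for any gene or list below. Lcn2 rose from 14.3 ± 7.27 to 1028 ± 534 CPM (n = 9 and 4, log2 fold change 6.14 ± 0.45, adjusted p = 1.51e-07). Tnf rose by 3.63 ± 0.29 (2.84e-07), Il1b by 1.95 ± 0.42 (0.00182), Cxcl10 by 1.78 ± 0.48 (0.00842), Tlr4 by 2.11 ± 0.25 (8.99e-06) and Adipor2 by 0.91 ± 0.15 (0.000224). Adipor1 did not pass (−1.28 ± 0.57, 0.0861). Without LPS mouse 7 it passed at −1.75. The genes that rose with the smallest p included Acod1, which makes itaconate in activated macrophages (0.558 ± 0.382 to 50.3 ± 10.2 CPM, 6.46 ± 0.32), Wfdc21 (5.68 ± 0.28), the lysosomal phosphatase Acp2 (3.36 ± 0.20) and the formyl peptide receptor Fpr1 (5.39 ± 0.33). Others came from near 0. The acute phase gene Saa3 had 16 counts in 7 of 9 PBS libraries and 164 ± 35.5 CPM with LPS, and the lipase Lipg 3 counts in 3 libraries and 87.4 ± 52.1. Inducible nitric oxide synthase, Nos2, had 2 counts in 1 library and 20.2 ± 10.6, and the protease Mmp14 11 counts in 5 libraries and 44.0 ± 24.2. Il10, at 0 counts with PBS, had 101 counts in 4 of 4 LPS libraries. Those that fell with the smallest p were the transcription factor Mef2c (−1.96 ± 0.17), Hpgd, which inactivates prostaglandins (−2.65 ± 0.24), Ralgps2, Mast4, the complement regulator Cd55, Fbxo32, Mturn and Nxpe3, the others between −2.62 and −1.998.

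Of 12353 genes tested in LPS against PBS, 4785 passed, 2577 upward and 2208 downward, with 1520 and 1650 changed at least 2-fold, and DESeq2 called 5579 and limma-voom 6171. Without TMM the median of all genes moved by 1.08 and the split was 5600 upward and 296 downward, so directions are relative to that median, and the calls of Mef2c (−0.89) and Nxpe3 (−0.91) ended. With the globin percentage as a covariate 3265 genes passed, and the call of Cxcl10 ended (1.59). Globin shares did not overlap between these groups (45.1% to 64.3% with PBS, 18.4% to 43.7% with LPS). This setting therefore cannot separate LPS from the globin share. The groups may differ in more than LPS if they belong to separate experiments.

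Among the lists, neutrophil markers rose in 23 of 24 members (24 adjusted over the list alone; median log2 fold change 3.30, camera adjusted p = 6.59e-17, 0.238 with an estimated correlation), with Fpr2 at 4.88 ± 0.36. Immature neutrophil granule genes rose in 9 of 9 (9; 4.99, 3.77e-06, 0.227), with Olfm4 at 6.25 ± 0.55 and Ngp at 5.58 ± 0.90. B cell markers fell in 24 of 24 (24; −2.50, 6.59e-17, 0.238), with the IgE receptor Fcer2a at −3.55 ± 0.38 and the IgM receptor Fcmr at −3.07 ± 0.33. T cell markers fell in 23 of 24 (24; −2.21, 6.24e-14, 0.238), with the homing receptor Ccr7 at −3.07 ± 0.32 and Cd5 at −2.54 ± 0.26. Type I interferon-stimulated genes rose in 29 of 34 (29; 1.78, 4.89e-10, 0.323), with Bst2, which tethers budding viruses, at 2.74 ± 0.21. Monocyte markers rose in 13 and fell in 1 of 21 (0.87, 0.000975, 0.402), with the Fc receptor Fcgr4 at 3.08 ± 0.27. NK cell markers rose in 8 of 18 (9; 0.81, 0.000359, 0.402), with granzyme B, Gzmb, at 2.78 ± 0.41 and Prf1 at 2.08 ± 0.24. Proliferation genes rose in 24 of 26 (24; 2.18, 3.11e-10, 0.238), with Aurkb at 2.81 ± 0.30 and Top2a at 2.88 ± 0.36.

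Signalling lists also rose with LPS, in RNA where the mix of cells also shifted. Cytokines and chemokines rose in 10 of 16 (10 rose and 1 fell adjusted over the list alone; median 1.86, camera adjusted p = 0.000123, 0.138 with an estimated correlation), with Cxcl2 at 5.46 ± 0.60 and Ccl2 at 5.11 ± 0.58. NF-kB target genes rose in 18 of 27 with 3 that fell (1.01, 1.67e-07, 0.124), and TLR4 signalling components in 12 of 25 (0.49, 0.000165, 0.152), with the co-receptor Cd14 at 4.79 ± 0.46. Inflammasome components rose in 6 of 12 with 2 that fell (0.81, 0.0167, 0.238), with Casp4 at 2.07 ± 0.28. Feedback inhibitors rose in 10 of 19 (0.87, 0.000112, 0.124), with Hmox1 at 3.49 ± 0.26 and Socs3 at 2.76 ± 0.24. Unfolded protein response genes rose in 12 of 21 with 1 that fell (0.92, 0.000775, 0.195), with Xbp1 at 1.63 ± 0.18. Sterol and fatty acid synthesis genes rose in 12 of 22 with 2 that fell (0.57, 0.00430, 0.251), with the LXR receptor Nr1h3 at 5.57 ± 0.35. Interferon-gamma-induced genes rose in 9 of 22 with 1 that fell (0.39, 0.0271, 0.402), where Gbp2 stood at 3.82 ± 0.47 and Ciita, the activator of MHC class II genes, at −2.58 ± 0.38, and heat shock genes rose in 7 of 12 (0.59, 0.0374, 0.402). Without the libraries of few detected genes the interferon-gamma call ended (0.27, adjusted p = 0.0607), and without TMM the heat shock call (1.73, 0.0844). With the globin covariate, which cannot be separated from LPS here, the monocyte (0.61, 0.0574), NK cell (0.21, 0.413), sterol (0.33, 0.472), heat shock (0.13, 0.472) and mitochondrial (−0.06, 0.366) calls ended. The interferon-gamma call ended without LPS mouse 7 (0.43, adjusted p = 0.0690) and the heat shock call without PBS mouse 3 (0.58, 0.0604) or LPS mouse 2 (0.47, 0.0522) or 6 (0.55, 0.0997). The adiponectin list did not pass (4 rose and 2 fell of 19; 0.04, 0.638), though Ppard (1.23 ± 0.15) and the kinase subunit Prkaa1 (0.94 ± 0.17) rose.

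Platelet markers fell with LPS in 14 of 23 (19 adjusted over the list alone; median −2.05, camera adjusted p = 6.26e-05, 0.505 with an estimated correlation), with the contractile regulator Mylk at −3.04 ± 0.66. The erythroid list had a median of −1.03 with 4 genes that fell and 1 that rose of 29 (0 adjusted over the list alone; 0.00171, 0.586), beside a lower globin share. With the globin percentage as a covariate, which cannot be separated from LPS here, the platelet median was 1.31. The erythroid median was 0.09 without TMM, −0.56 without LPS mouse 6, which ended the call (adjusted p = 0.0565), and −1.68 without LPS mouse 7. Without the libraries of few detected genes it was −0.30 (adjusted p = 0.166), and the platelet median was −1.07. Ribosomal proteins fell in 22 of 48 (25; −0.65, 4.52e-08, 0.402, with a median of 0.50 without TMM and −0.54 relative to all genes) and mitochondrially encoded genes in 10 of 10 (10; −1.37, 5.38e-05, 0.238). Lists that missed the threshold were dendritic cells (2 rose and 5 fell of 12; 0.0938), eosinophils and basophils (0 and 2 of 6; 0.0800), fatty acid oxidation (7 and 2 of 23; 0.416), and sphingolipids (9 and 3 of 24; 0.302). Others were NRF2 targets (10 and 4 of 22; 0.0758), the nuclear respiratory chain (9 and 5 of 42; 0.379), autophagy (3 and 5 of 22; 0.326), and immediate early genes (7 and 2 of 18; 0.0796). The rest were glucocorticoid-responsive genes (5 and 2 of 13; 0.170), circadian clock genes (3 and 5 of 13; 0.326), muscle (1 and 2 of 5; 0.328), adipocyte (2 and 1 of 6; 0.507), endothelial (1 and 4 of 8; 0.450) and sex-linked transcripts (0 and 1, Uty, of 4; 0.415). The median and mean differed in sign for the adiponectin and respiratory chain lists.

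**Figure D3:**
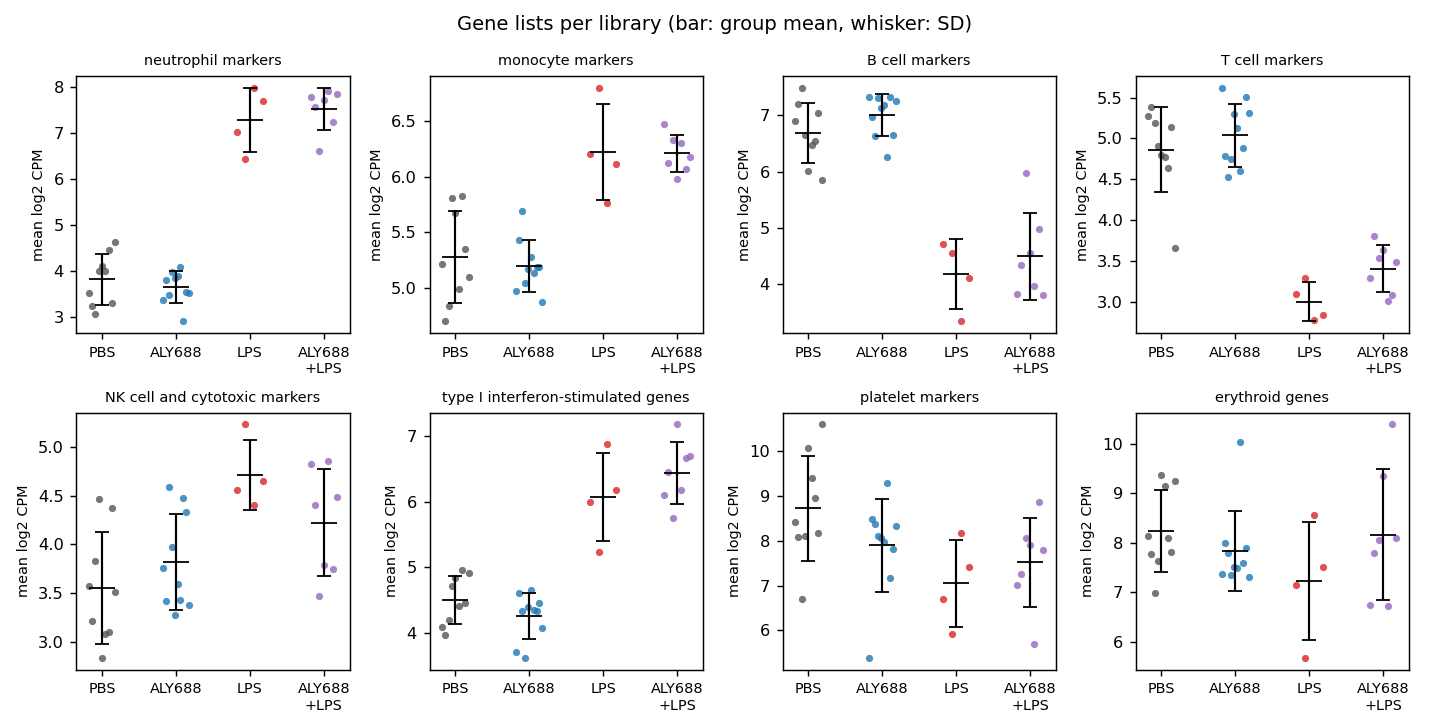
Mean log2 CPM over the members of 8 gene lists in each library, with the 4 groups on the x axis, dots for mice, bars for the group mean and whiskers for the SD. Neutrophil scores averaged 3.82, 3.65, 7.28 and 7.52 with PBS, ALY688, LPS and both, and B cell scores 6.68, 7.01, 4.18 and 4.50. Scores are TMM-scaled, and without TMM the LPS against PBS median of the erythroid list changes sign, as do ALY688 medians of the interferon, neutrophil, monocyte and erythroid lists without LPS and of the interferon, neutrophil, platelet, B and T cell lists with LPS. The median of all genes then moves by 1.08 for LPS against PBS, and by 0.47 and −0.49 for ALY688 without and with LPS. Relative to all genes these lists keep their direction.

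The same contrast was made in mice given ALY688, with LPS against without. Here too, a change in the mix of cells was not separated from a change within cells. Lcn2 rose from 14.2 ± 8.89 to 1207 ± 529 CPM (n = 10 and 7, log2 fold change 6.39 ± 0.45, adjusted p = 5.99e-10). Il1b rose by 2.73 ± 0.23 (6.47e-09), Tnf by 3.32 ± 0.31 (6.01e-08), Tlr4 by 2.36 ± 0.13 (2.53e-11), Cxcl10 by 2.18 ± 0.33 (1.35e-05) and Adipor2 by 0.81 ± 0.08 (3.61e-08). Adipor1 did not pass (0.07 ± 0.56, 0.933), but did with the globin covariate (0.86). The genes that rose with the smallest p were Ampd3, an AMP deaminase (2.31 ± 0.08), the interferon-induced Ifitm1 (5.13 ± 0.18), Clec4e, a receptor for mycobacterial lipids (3.92 ± 0.15), Rab31, Entpd3, Klhl2, Dhrs9 and Igfbp6, which lay at 0.354 ± 0.354 CPM without LPS and 22.5 ± 4.58 with it. Those that fell were the cytokine receptor Il27ra (−1.84 ± 0.13), Cd72 (−1.94 ± 0.15), Dtx1, Gimap1, Itpr3, the kynurenine enzyme Kmo (−2.72 ± 0.22), Plekhn1 and Carmil2. Of 12266 genes 6504 passed, 3236 upward and 3268 downward (1845 and 1204 without TMM, where the all-gene median moved by 0.075), and DESeq2 called 6929 and limma-voom 7651.

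Gene lists in mice given ALY688 with and without LPS passed in 24 of 36 cases, 18 upward and 6 downward, and none held with an estimated correlation, where the smallest adjusted p was 0.225. Fry called 26 of 36 lists here and 26 in LPS against PBS, where 21 lists had passed camera. Neutrophil markers rose in 24 of 24 (24 adjusted over the list alone; median 3.79, camera adjusted p = 1.60e-18, 0.225 with an estimated correlation), with Fpr2 at 5.66 ± 0.29. Interferon-stimulated genes rose in 31 of 34 (31; 2.36, 8.47e-13, 0.225), with Oasl2 at 3.20 ± 0.23 and Rtp4 at 3.17 ± 0.23. B cell markers fell in 24 of 24 (24; −2.27, 1.04e-13, 0.283), with Spib at −2.20 ± 0.24, and T cell markers in 24 of 24 (24; −1.70, 2.24e-11, 0.276), with Cd4 at −2.12 ± 0.21. Proliferation genes rose in 22 of 26 (23; 1.28, 5.33e-06, 0.309), NF-kB target genes in 18 with 3 that fell of 27 (1.07, 4.69e-05, 0.308). Feedback inhibitors rose in 12 of 19 (0.91, 9.00e-05, 0.225), immature granule genes in 8 of 9 (2.52, 9.00e-05, 0.288) and monocyte markers in 14 with 1 that fell of 21 (1.09, 0.000245, 0.225). Members were the mitotic kinase Bub1 (2.80 ± 0.41), Anxa1, which limits neutrophil recruitment (3.29 ± 0.15), Il1rn, the IL-1 receptor antagonist (4.24 ± 0.30), and Treml4 (2.27 ± 0.12). TLR4 components rose in 13 with 3 that fell of 25 (0.35, 0.000973, 0.225), with the adaptor Myd88 at 2.03 ± 0.09. Cytokines rose in 9 with 1 of 13 (1.61, 0.00197, 0.225), with Cxcl2 at 7.41 ± 0.54. Inflammasome components rose in 8 with 1 of 12 (0.95, 0.00265, 0.225), unfolded protein response genes in 13 with 2 of 21 (0.76, 0.000973, 0.225). NRF2 targets rose in 10 with 1 of 22 (0.84, 0.00197, 0.309) and interferon-gamma-induced genes in 13 with 2 of 22 (0.51, 0.00787, 0.328).

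Smaller shifts also passed in this comparison. Ribosomal proteins fell in 15 of 48 (median −0.29, camera adjusted p = 0.00522, 0.608 with an estimated correlation), mitochondrially encoded genes in 7 of 11 (−0.73, 0.00845, 0.426). Immediate early genes rose in 9 with 3 that fell of 17 (0.47, 0.0202, 0.286) and heat shock genes in 7 of 11 (0.50, 0.0309, 0.320). With the globin covariate the ribosomal (−0.13, 0.146), mitochondrial (−0.43, 0.0606), heat shock (0.33, 0.0532), glucocorticoid (0.63, 0.0650), dendritic (−0.94, 0.0606) and muscle (−1.47, 0.123) calls ended, and without TMM the respiratory chain (0.33, 0.159), heat shock (0.60, 0.0672), fatty acid oxidation (0.59) and immediate early (0.53, both 0.05002) calls. Dendritic and muscle calls also ended with RLE factors (−1.04, 0.0544 and −1.51, 0.0574) and without the libraries of few detected genes (−1.06, 0.0711 and −1.49, 0.0525). Several calls ended on leaving out single libraries. Fatty acid oxidation (12 rose and 4 fell of 23; 0.47, 0.0391, 0.308) ended without ALY688 mouse 8 (0.44, 0.0519) or 9 (0.36, 0.0724) or mouse 8 of the combined group (0.35, 0.0502). The nuclear respiratory chain (14 and 0 of 42; 0.18, 0.0391, 0.608) ended without ALY688 mouse 8 (0.13, 0.0761), 9 (0.15, 0.0580) or 10 (0.13, 0.0533) or combined mouse 10 (0.15, 0.0625), with a median of 0.27 without ALY688 mouse 7. Glucocorticoid-responsive genes (7 and 2 of 13; 0.67, 0.0451, 0.394) ended without ALY688 mouse 2, 6, 7 or 8 or combined mouse 1 or 3, with adjusted p of 0.0502 to 0.0676 and medians of 0.49 to 0.80. Dendritic cell markers (2 and 6 of 12; −1.04, 0.0485, 0.373) ended in 9 leave-outs (ALY688 mice 2, 3, 7, 8 and 9, combined mice 3, 4, 6 and 8; 0.0502 to 0.0829, medians −1.13 to −0.88). Muscle transcripts (1 and 5 of 7; −1.52, 0.0497, 0.309) ended in 13 of 17, all but ALY688 mouse 10 and combined mice 4, 6 and 7, with 0.0513 to 0.171 and medians of −1.81 to −1.37. The dendritic cell gene Cd209a fell to 13 counts in 5 of 7 libraries from 4.82 ± 2.07 CPM. NK cell (4 rose and 2 fell of 18; 0.23, 0.329), platelet (0 and 0 of 23; −0.30, 0.298), erythroid (6 and 0 of 30; 0.34, 0.384), and adiponectin lists (6 and 4 of 19; −0.05 and 0.04 without TMM, 0.522) did not pass. Neither did sterol (8 and 5 of 22; 0.483), sphingolipid (11 and 7 of 25; 0.181), and autophagy genes (5 and 1 of 22; 0.187). The same held for circadian (3 and 7 of 13; 0.298), eosinophil and basophil (1 and 5 of 7; 0.0663), adipocyte (4 and 1 of 6; 0.190), endothelial (0 and 0 of 5; 0.492) and sex-linked transcripts (0 and 1, Kdm5d, of 4; 0.637). Adjusted over the lists alone, 430 members of all lists passed here and 431 in LPS against PBS.

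Both LPS comparisons share no library. Of 12075 genes tested in both, 2248 rose in both, where 666 would be shared by independent lists of 2494 and 3224, and 1387 fell in both, where 573 would be shared by lists of 2173 and 3184. In all, 2 went opposite ways. Across genes, which are not independent replicates, the fold changes correlated at r = 0.85 and rho = 0.80.

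Whether ALY688 acts differently with and without LPS was tested as the interaction over all 4 groups. No gene passed in edgeR (0 of 13476, smallest adjusted p = 0.244, 1217 at an unadjusted p under 0.05 against 674 expected for independent genes). As many as 1217 were reached in 7 of 100 labellings of the mice, the real one included, and the others had a median of 458. An excess over chance was not shown. The 1217 became 413 without the libraries of few detected genes, 419 with 1 surrogate variable and 299 with the globin covariate, all below 674. Klra8 came nearest, at 6.44 ± 1.98 CPM with PBS, 10.9 ± 3.32 with ALY688, 13.9 ± 3.83 with LPS and 7.51 ± 2.79 with both (−1.57 ± 0.31, adjusted p = 0.244). The immunoglobulin gene Ighg2c came next and had 3 counts in 3 libraries with PBS, 53 in 8 of 10 with ALY688, and 1.11 ± 0.820 and 0.184 ± 0.213 CPM with LPS and with both (adjusted p = 0.336). Tspoap1 (−1.68 ± 0.38, 0.399) and the pseudogene Rps12-ps4 (2.15 ± 0.49, 0.399) followed. DESeq2 called 4 genes (1558 at unadjusted p under 0.05), named after their values were seen: Tspoap1, Ighg2c, Klra8 and Rps12-ps4, each at an adjusted p of 0.0375. Limma-voom called 2 (1565), Tspoap1 (adjusted p = 0.0134) and Stxbp4 (−2.61, 0.0434), the latter also named after the fact. Without mouse 1 of the combined group edgeR called Klra8 (−1.73, adjusted p = 0.0379). For the inflammatory genes the interaction was −0.30 ± 0.46 for Tnf, 0.79 ± 0.48 for Il1b, 0.26 ± 0.60 for Lcn2, 0.25 ± 0.28 for Tlr4 and 0.38 ± 0.59 for Cxcl10. For the receptors it was −0.10 ± 0.15 for Adipor2 and 1.36 ± 0.83 for Adipor1, with adjusted p of at least 0.511. Without mouse 8 of the combined group that of Adipor1 was 0.71.

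In the interaction 14 of 36 lists passed camera, 11 upward and 3 downward, none with an estimated correlation (smallest adjusted p = 0.689) and none by fry (smallest 0.318). Erythroid genes were higher in 30 of 30 (median 1.60, camera adjusted p = 8.2e-10, 0.689 with an estimated correlation), with Tfrc at 1.13 ± 0.42. Platelet markers were higher in 23 of 23 (1.56, 5.08e-09, 0.689), with Selp at 1.70 ± 0.72. Without mouse 8 of the combined group the erythroid median became 0.93. Proliferation genes were lower in 24 of 26 (−0.82, 1.68e-05, 0.689), with Aurkb at −1.60 ± 0.43. Sterol and fatty acid synthesis genes were lower in 19 of 23 (−0.35, 6.20e-05, 0.689), with Scd2 at −0.81 ± 0.29, and NK cell markers in 16 of 18 (−0.48, 1.68e-05, 0.689, and −0.27 without LPS mouse 6), with Eomes at −1.07 ± 0.34. The others were higher with TMM and lower without it, where the median of all genes moved by −0.96. Without TMM the all-gene median was −0.998, and each of these lists stayed above it. They were interferon-stimulated genes (0.64 and −0.42, 3.11e-07, 0.689), ribosomal proteins (0.32 and −0.81, 2.63e-07, 0.689), autophagy genes (0.81 and −0.35, 6.20e-05, 0.689), and neutrophil markers (0.46 and −0.47, 0.000715, 0.778). Others were T cell markers (0.43 and −0.63, 0.00368, 0.778), mitochondrially encoded genes (0.66 and −0.50, 0.00368, 0.689), and NRF2 targets (0.40 and −0.70, 0.0223, 0.698). The rest were fatty acid oxidation (0.22 and −0.82, 0.0367, 0.689) and glucocorticoid-responsive genes (0.42 and −0.49, 0.0475, 0.689). Without LPS mouse 6 the neutrophil call ended (0.21, adjusted p = 0.158) and medians became 0.42 for interferon and 0.26 for NRF2 genes. The neutrophil median became 0.29 without PBS mouse 9 and 0.28 without LPS mouse 2, the mitochondrial 0.39 without combined mouse 8, and the ribosomal 0.19 and 0.20 without LPS mice 7 and 8. Without the libraries of few detected genes the erythroid and platelet medians were 0.20 and 0.33, and the NRF2 (0.12, adjusted p = 0.178) and mitochondrial (0.09, 0.299) calls ended. With the globin covariate the platelet (−0.14, 0.159), interferon (0.11, 0.777), neutrophil (0.18, 0.475), autophagy (−0.05, 0.145), fatty acid oxidation (0.11, 0.150), NRF2 (−0.09, 0.133) and mitochondrial (−0.15, 0.150) calls ended. With 1 surrogate variable the erythroid (0.08, 0.499), platelet (−0.08, 0.722), neutrophil (0.13, 0.611), fatty acid oxidation (0.12, 0.0809), NRF2 (−0.01, 0.476), mitochondrial (−0.02, 0.964) and autophagy (0.04, 0.721) calls ended. Without TMM the T cell (0.0982), fatty acid oxidation (0.613), mitochondrial (0.773), glucocorticoid (0.113) and ribosomal (0.659) calls ended. The NRF2 call ended without PBS mouse 5 (0.30, 0.0502), 7 (0.35, 0.0507) or 9 (0.25, 0.0567). The fatty acid oxidation call ended in 11 of 30 leave-outs (PBS mice 3, 4, 7 and 8, ALY688 mice 9 and 10, LPS mice 7 and 8, combined mice 1, 7 and 10; medians 0.17 to 0.23) and the glucocorticoid call in 16 (PBS mice 2, 3, 4, 7 and 9, ALY688 mice 1, 2, 5, 6, 7, 8 and 10, LPS mice 2 and 6, combined mice 1 and 3; medians 0.28 to 0.41). Adjusted over the list alone, 6 members passed: Klra8, Eomes, Aurkb, and the immature granule genes Mpo and Prtn3 lower, and Uty higher. Mpo counts came mostly from 1 LPS mouse, with a range of 0.0479 to 93.9 CPM among the 4.

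Inflammation lists did not pass in the interaction: cytokines (median 0.14, camera adjusted p = 0.296), NF-kB target genes (0.07, 0.912), TLR4 components (−0.06, 0.759), inflammasome components (0.17, 0.422), interferon-gamma-induced genes (0.22, 0.285) and feedback inhibitors (0.13, 0.279). B cell markers (0.29, 0.448), monocyte markers (0.09, 0.307) and the adiponectin list (−0.10, 0.768) did not pass either. The median, mean or test differed in sign for the NF-kB, TLR4, adiponectin and unfolded protein lists. Across 11481 genes, the log2 fold changes for ALY688 without and with LPS had a Spearman rho of −0.342 and a Pearson r of −0.344. These comparisons share no library. Of 100 labellings of the mice, the real one included, 15 had a rho as far from 0 (permutation p = 0.15), and those relabelled ran from −0.535 to 0.513. Without LPS mouse 6 rho was −0.178.

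Positions in GRCm38 of the genes fixed in advance, all protein coding and given for the whole gene, were chromosome 2 from 32384633 to 32388252 on the minus strand for Lcn2 (ENSMUSG00000026822), chromosome 2 from 129364570 to 129371139 (minus) for Il1b (ENSMUSG00000027398). They were chromosome 17 from 35199381 to 35202007 (minus) for Tnf (ENSMUSG00000024401), chromosome 4 from 66827584 to 66930284 (plus) for Tlr4 (ENSMUSG00000039005). The others were chromosome 5 from 92346638 to 92348889 (minus) for Cxcl10 (ENSMUSG00000034855), chromosome 1 from 134415378 to 134433351 (plus) for Adipor1 (ENSMUSG00000026457) and chromosome 6 from 119353150 to 119417704 (minus) for Adipor2 (ENSMUSG00000030168). Klra8 (ENSMUSG00000089727) spans chromosome 6 from 130115226 to 130129898 (minus), and Trac (ENSMUSG00000076928) chromosome 14 from 54220521 to 54224206 (plus).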

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

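The relabelling of the mice for the correlation was fixed before the data were examined, while the other tests of patterns were chosen after the patterns had been seen, with predictions written before their values were looked at. A sample far from the others of its group was found in 11 of 90 sets of values. For sets with a normal spread about 1 in 20, or 4.5, would be expected. The sets share libraries and were not checked for a normal spread, so this does not measure an excess over chance. Mouse 7 of the ALY688 group stood apart in 4 sets: 14630 genes with a count (others 17094 to 18174), 10893714 total counts (others 11712834 to 12514008), Adipor1, an adiponectin receptor, at 6469 CPM (others 882 to 1408), and a mean log2 CPM of erythroid genes of 10.0 (others 7.31 to 7.99). Mouse 8 given ALY688 with LPS had Adipor1 at 5416 CPM (others 484 to 2591) and Tlr4, the LPS receptor, at 15.5 CPM (others 24.9 to 30.4). The other samples were ALY688 mouse 3 for the adiponectin-binding Cdh13 (0.605 CPM, others 0 to 0.192, all near the floor), ALY688 mouse 8 for Tnf (3.70 CPM, others 0.789 to 2.34), PBS mouse 9 for Tlr4 (10.1 CPM, others 3.19 to 6.64) and for T cell markers (mean log2 CPM 3.66, others 4.64 to 5.39), and PBS mouse 6 for immature neutrophil granule genes (2.63, others −0.34 to 1.01).

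The first pattern is that genes tended to move in opposite directions with ALY688 alone and with ALY688 under LPS, at a Spearman rho of −0.342 across genes. The assignment of mice to groups by chance could give this, since 15 of 100 labellings, the real one included, lay as far from 0 and the farthest relabelled one reached −0.535. A difference in the share of red cell RNA is consistent with the pattern, since rho was −0.0138 with the globin percentage as a covariate, although that percentage may itself be changed by ALY688. A response to ALY688 that depends on LPS is the biological explanation in this design, and the interaction test, with 0 genes past the threshold in edgeR, did not single it out.

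The second pattern is that medians of platelet and erythroid transcripts were lower with ALY688 alone and higher with ALY688 under LPS. Scores per mouse did not pass exact permutation tests without and with LPS (platelet p = 0.126 and 0.467, erythroid 0.295 and 0.279). No list call held with an estimated correlation or fry. Scaling could not be weighed. Without TMM the interaction median of the platelet markers was 0.163 instead of 1.56, between the bounds set beforehand. That of all genes was −0.998, and relative to it the platelet median was 1.16. Libraries with few detected genes could not be weighed either. Without these libraries the erythroid median was 0.204 instead of 1.60, which met the prediction written for them as the cause. That outcome was set aside by a rule not among the written predictions. Detected genes and the erythroid score correlated at r = −0.946 within groups, so leaving these libraries out selects on red cell RNA itself. The amount of platelets and young red cells carried into each blood sample was not measured apart from these transcripts, so handling of the blood and a biological change in these cells were not separated.

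The last pattern is that mice 4 and 8 given ALY688 with LPS lay nearest to the libraries without LPS. An animal that received no LPS is unlikely. The lowest mean log2 CPM over 1520 genes that rose with LPS was 3.55 in this group (mouse 4, with mouse 8 at 3.57). The highest value among the 19 libraries without LPS was 2.34. The score holds only genes that rose with LPS, so it cannot show a missed dose of ALY688 or a swap with the LPS group. A weaker response to ALY688 with LPS in these mice has no test in this design.

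For the counts of changed genes, other splits of the same libraries were compared with the real ones. In ALY688 against PBS and ALY688 with LPS against LPS, all 100 of 100 splits gave at least the 0 genes of the real grouping, as any split must, and other splits reached 0 and 2 genes. In the interaction 100 of 100 did, with up to 283 genes in another split. For these 3 the count of genes at an unadjusted p under 0.05 was reached by 6, 48 and 7 of 100 splits, the real one included (1250, 463 and 1217 genes). Only 1 of 100 splits, the real one, reached the 4785 genes of LPS against PBS (highest other 1356) and the 6504 genes of the same contrast in mice given ALY688 (highest other 328), so an arrangement of mice by chance is unlikely for these.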

How the results depend on the processing

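Scaling without TMM, the omission of libraries with few detected genes and the globin percentage as a covariate were chosen after the data were seen, as were RLE size factors for the lists and a surrogate variable for the lists and the correlation. No gene passed in ALY688 against PBS or in ALY688 with LPS against LPS under any setting or leave-out. Leaving out 1 library at a time gave 3722 to 4921 genes in LPS against PBS, 6058 to 6962 in the same contrast with ALY688 and 0 to 1 in the interaction, and 12 to 16, 8 to 14, 20 to 23, 19 to 24 and 11 to 15 lists past camera in the 5 comparisons, in the order ALY688 against PBS, ALY688 with LPS against LPS, LPS against PBS, ALY688 with LPS against ALY688, and interaction. The Spearman correlation of the ALY688 effects ran from −0.426 to −0.178 in leave-outs. It was −0.436 over genes with a mean log2 CPM above 3, −0.340 with RLE size factors and −0.303 without TMM, and 0.000988 with 1 surrogate variable, −0.0368 without the libraries of few detected genes and −0.0138 with the globin covariate. The interaction count became 4 with DESeq2 and 2 with limma-voom, and the count of ALY688 with LPS against ALY688 became 3049 without TMM. With a correlation estimated from these libraries the count of lists was 0 in all 5 comparisons, so the camera calls rest on the preset 0.01. Fry called 0 lists in both ALY688 comparisons and the interaction, and 26 in each LPS comparison. The count of lists in ALY688 against PBS became 9 with 1 surrogate variable, 8 without TMM and 8 with the globin covariate, and that in ALY688 with LPS against LPS became 7 without the libraries of few detected genes. The labels do not say whether mice with the same replicate number in different groups are linked. Deviations from the group means correlated at −0.501 to 0.297 between same-numbered libraries, over few pairs, which does not settle it. A replicate block on these numbers gave 0, 0, 3531, 4870 and 0 genes and 15, 11, 20, 24 and 14 lists. In the first 4 comparisons the block compared only mice whose number occurs in both groups, with 9, 3, 4 and 7 such numbers. The other mice do not enter those contrasts. Of the main list calls 13 of 14, 9 of 11, 20 of 21, 23 of 24 and 13 of 14 also passed with the block. List medians reversed with 1 surrogate variable for erythroid genes in ALY688 against PBS (0.22) and platelet markers in ALY688 with LPS against LPS (−0.16), and with the globin covariate for erythroid genes (0.42) in the former, for platelet (−0.39) and erythroid (−0.24) genes in the latter, for platelet (1.31) and erythroid (1.29) genes in LPS against PBS, and for erythroid genes in the interaction (−0.68). The erythroid list holds the globin genes that this covariate measures, so its reversals with the covariate follow from the setting and test nothing. A list counted as reversed only where it passed in both fits, a gene where it passed in either. In LPS against PBS, 20 genes turned in sign in this way. Only Acsl1 passed in the alternative fit (adjusted p = 0.015), while the calls of the others ended (0.135 to 0.906). Without TMM the genes that turned were Acadm (0.56), mt-Nd6 (0.0601), mt-Nd2 (0.23), mt-Nd5 (0.0596), Rps15a (0.15) and Uty (0.46), where all genes moved by 1.08. With the globin covariate they were Gp6 (0.87), Ppbp (0.62), Fech (0.57), Bnip3l (1.01), Hbb-bt (0.68), mt-Co3 (0.21), Gabarapl2 (0.84), Gabarapl1 (0.90), Hspd1 (−0.20), Eno3 (−0.16), Acsl1 (1.66), Tie1 (1.04), Vwf (0.99) and Esam (1.52). Hbb-bt is among the globin genes that the covariate measures, so its turn follows from the setting. For the other genes the cause was not tested. Globin shares of PBS and LPS mice did not overlap. In LPS against PBS this covariate therefore cannot separate LPS from the globin share, for genes or lists. Among other named genes in settings other than leave-outs, 80 results were weaker and 15 stronger in LPS against PBS, 23 and 14 in ALY688 with LPS against ALY688, and 0 and 5 in the interaction, and in leave-outs 45 and 3, 1 and 5, and 0 and 1. Results past the threshold in neither fit were counted as unchanged even where their sign turned, which it did 139, 144, 8, 21 and 136 times in the 5 comparisons. Simulated 2-fold changes were recovered in 25.4% of genes in ALY688 with LPS against LPS, with 4 and 7 mice, and in 65.7% in ALY688 against PBS, with 9 and 10.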
